A study of Homo sapiens with 8 samples.

How the data were processed

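Total RNA of JJN3 cells was sequenced in 8 libraries, 2 for each of 4 groups: non-silencing or ILF2 shRNA, untreated or with 25 µM melphalan for 10 h. Groups and replicate numbers were taken from the sample titles and source names. Per the labels' design text the replicates were independent, but nothing says whether they came from separate cultures, so the authors' p values may measure technical spread only. RNA was extracted with the RNeasy Mini kit. The labels name 2 different library kits, Ovation RNA-Seq System V2 in the series text and an Illumina total RNA kit in the sample text, and which was used was not resolved. Whether reads kept strand is not given in the sources used here, so overlapping and antisense genes are uncertain.

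Per the labels, the libraries were run as paired ends of 76 bases on an Illumina HiSeq instrument, with 60000000 to 160000000 reads each. Per the labels' design text the reads were mapped with TopHat2 to GRCh37 (hg19) with up to 2 mismatches per read end, and differential splicing was called with MATS at an FDR under 0.05. TopHat2 and the builds GRCh37 and hg19 are also named in the submitters' processing notes. The versions of TopHat2 and MATS, the gene annotation and the read minimum are not given in the sources used here. MATS takes events from an annotation and from junction reads, so deeper libraries give more testable events and smaller p values.

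The authors' deposited tables, 1 for each of the 3 comparisons, hold for each passing event a gene symbol, chromosome, strand, p value, FDR and event type. They hold 0 columns of values per library, so inclusion levels, junction counts, event coordinates and the depth behind each event were not analysed here. Tests planned on these were not run: the direction of inclusion changes, minimum changes of inclusion, a junction read minimum, overlap by coordinates, replicate agreement and leaving out a library. Event numbers in the tables name different genes from table to table and were not used to match events. Genes were matched by symbol. In 1, 2 and 2 events of the untreated knockdown, melphalan-treated knockdown and melphalan tables the gene symbol had been turned into a date by a spreadsheet. These cells were kept as separate genes and never named.

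The number of events tested was recovered from the authors' FDR, which followed the Benjamini-Hochberg formula within each event type. FDR times rank divided by p gave the same whole number, within 0.5, for 70.7 to 94.1% of the events of each type and table, and a smaller one for the rest. The formula lowers an FDR to that of the next event where that is smaller, and with this step included the recovered numbers gave back the deposited FDR of 3154 of 3154 events with a p above 0, within 0.1%. It came to 24698, 28849 and 28467 skipped exons and to 4184, 5373 and 5351 mutually exclusive exons in the untreated knockdown, melphalan-treated knockdown and melphalan comparisons. Retained introns had 354, 365 and 365 tests, alternative 5′ splice sites 1045, 1067 and 1081, and alternative 3′ splice sites 1113 and 1155 in the last 2. The 1 alternative 3′ splice site of the untreated knockdown comparison had a p of 0, so its number could not be recovered. Tested on simulated data for the 14 type and table lists with recovered numbers (354 to 28849 events), the step returned the right number in 280 of 280 simulations. The simulated FDRs came from the same formula, with no passing event missing, so this checks the calculation only.

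The percent of tests that passed was given with 95% exact (Clopper-Pearson) binomial intervals, which cover counting error over events only. Percents and shares were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment, over 13 tests for pass rates, 15 for shares of event types (1 event per gene and type) and 45 for gene lists. Ratios have 95% intervals on the log scale. Events and genes are not biological replicates, events of the same gene depend on each other, and the lists share genes, so these p values describe the lists and are too small as measures of the conditions.

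The groups, tests, alternatives, 14 gene lists and the rule for named genes were fixed before the data were examined. The pass rates, the fixed p of 0.0005, the matching of shared genes by gene and type, and the tests that the closing section names as such were added after. Of the lists, 5 covered DNA repair and damage signalling (237 symbols together, 20 to 80 each). The other 9 covered p53 targets (34 symbols), splicing regulators (202), RNA decay and 3′ end processing (67), apoptosis (61) and cell cycle and mitosis (166). They also covered chromatin (139), plasma cell and myeloma genes (59), interferon response (53), and ribosomal proteins and translation factors (128). A longer list can hold more listed genes, so counts do not rank the lists. The rule named, for each comparison, the 12 genes with the lowest FDR (then p, then symbol, since the tables hold no inclusion levels), up to 12 DNA repair and damage signalling genes, ILF2 if listed, and up to 4 genes of each other list. It also named 6 genes shared by the knockdown comparisons, which without coordinates were matched by gene and type and ranked by the larger of both FDRs. Genes named beyond it (DNA repair genes in both knockdown lists, genes listed with the same event type in all 3 comparisons, and genes with the most events) were chosen after their values were seen. Some genes that the rule names are not reported here.

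Gene positions came from GENCODE 44 lifted to GRCh37. Of 1761 listed genes 1749 (99.3%) were matched, 1606 by symbol and 143 through older symbols, with 0 conflicts of chromosome or strand. Positions are those of whole genes, 1-based. Whether an event lay in a coding exon or an untranslated region was not analysed here. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. Alternatives were an FDR under 0.01 or 0.001, the fixed p, genes in place of events, all events in place of 1 per gene and type, matching by gene and type, skipped exons alone, and homologous recombination and Fanconi genes alone.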

Results

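Splicing was measured by RNA sequencing in JJN3, an established multiple myeloma cell line. The cells carried a lentiviral short hairpin RNA (shRNA) against ILF2, an RNA-binding protein, or a non-silencing shRNA. They were untreated or exposed to melphalan, an alkylating drug used in myeloma, at 25 µM for 10 h. The 4 resulting groups held 2 libraries each, 8 in all. The labels give 60000000 to 160000000 reads of 76 bases per library. The junction reads behind each event are unknown, because the authors' deposited tables list only events that passed, with a p value and a false discovery rate (FDR). Direction and size of the change in exon or intron inclusion were therefore not analysed here, nor were ILF2 RNA levels, so the knockdown itself was not checked. Comparisons were made for ILF2 against non-silencing shRNA in untreated cells, for ILF2 against non-silencing shRNA in melphalan-treated cells, and for untreated against melphalan-treated cells. Which shRNA the cells of the last comparison carried, and so how many libraries it used, is not given in the sources used here.

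The untreated knockdown comparison asks which transcripts are spliced differently between cells with ILF2 and with non-silencing shRNA when no drug is given. It listed 646 events in 500 genes, and 82 of these genes had more than 1 event. In the authors' deposited table, the lowest FDR, printed as 0, belonged to skipped exons of AFMID (a kynurenine pathway enzyme), FDPS (farnesyl diphosphate synthase of the isoprenoid pathway), ITGB7 (integrin beta 7) and RPS3A. Mutually exclusive exons of DNM2 (the endocytic GTPase dynamin 2), PKM (pyruvate kinase, whose muscle-type and proliferating-cell isoforms arise from alternative exons) and RPS3, and an alternative 3′ splice site of ESYT1, were also printed at FDR 0 in the authors' deposited table. These were followed in the authors' deposited table by a retained intron of CREBZF at FDR 3.93e-14, mutually exclusive exons of the kinase gene FYN at 8.13e-13 and a skipped exon of MBNL1, itself a splicing regulator, at 9.14e-13. A printed 0 stands for a p below 1.11e-16, the smallest value above 0 in the tables. Without event coordinates it is unknown which exons of PKM or the other genes were listed. The comparison held 301 skipped exons, 303 mutually exclusive exons, 24 retained introns, 17 alternative 5′ splice sites and 1 alternative 3′ splice site.

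DNA repair and damage signalling genes made up 14 of the 500 genes of the untreated knockdown comparison. ERCC1, a subunit of the nucleotide excision repair endonuclease (chromosome 19, 45910592 to 45982086, minus strand), led them with 3 events and an FDR of 4.29e-05 in the authors' deposited table. Mutually exclusive exons of the chromatin assembly gene CHAF1B had an FDR of 0.000307 in the authors' deposited table. A skipped exon of CHEK1, the checkpoint kinase that responds to stalled replication (chromosome 11, 125495058 to 125546150, plus strand), had an FDR of 0.000837 in the authors' deposited table. The homologous recombination gene RAD54L had 0.00103, and APEX2, LIG1, TOPBP1, FANCD2, OGG1 and RPA2 lay between 0.00503 and 0.0366 in the authors' deposited table. By list, base excision, mismatch and direct repair (51 symbols) had 5 genes. Homologous recombination and Fanconi (80), nucleotide excision repair (29), and damage checkpoint and signalling (57) had 3 each. No end joining gene was listed, against 4 in the melphalan-treated knockdown comparison, a difference that did not pass its test.

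The other lists range from 34 symbols (p53 targets) to 202 (splicing regulators), so counts of their listed genes do not rank them. Among them, ribosomal proteins and translation factors (128 symbols) had the most members in the untreated knockdown comparison, 23 genes. They included RPS3, RPS3A, the translation initiation scaffold EIF4G1 at FDR 1.99e-09 and the elongation factor EEF1D at 2.30e-09 in the authors' deposited table. Reads of ribosomal protein genes can also match processed pseudogenes, so these calls are uncertain. Cell cycle and mitosis genes numbered 17, led by the condensin subunit SMC4, CENPK, CEP192 and LIN9. Splicing regulators numbered 15, led by MBNL1, HNRNPK at FDR 3.13e-09, SRSF7 at 3.79e-08 and a retained intron of LUC7L3 at 2.49e-07 in the authors' deposited table. Chromatin genes numbered 12, led by INO80E, KAT6A, EHMT2 and CHD4. RNA decay and 3′ end processing had 6 genes, among them PAPOLA, XRN1, DIS3 and SYMPK. Apoptosis had 3 (BID, DAP3 and BCL2L12), plasma cell and myeloma genes 3 (DIS3, IKZF3 and IKZF1), interferon response 2 (IRF3 and BST2) and p53 targets 1 (GADD45A). ILF2 itself was not listed.

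The melphalan-treated knockdown comparison asks the same of cells given the drug. It listed 1210 events in 927 genes, 178 of them with more than 1 event. The authors' deposited table prints 39 events at p 0, and among these ties the first genes by symbol were AKNA, ANXA6, APEH, ATP5A1, C19orf60, CDK6, CLDND1, CREBZF, CYBA, DNM2, EEF1D and FAM49B. Of these 12, AKNA, ANXA6, APEH, ATP5A1, C19orf60, the G1 cyclin-dependent kinase CDK6, CYBA, DNM2 and FAM49B were listed with mutually exclusive exons, CLDND1 with an alternative 5′ splice site, CREBZF with a retained intron and EEF1D with a skipped exon. By type the comparison held 368 skipped exons, 706 mutually exclusive exons, 42 retained introns, 80 alternative 5′ splice sites and 14 alternative 3′ splice sites.

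The melphalan-treated knockdown comparison listed 31 DNA repair and damage signalling genes. RUVBL2, an ATPase of chromatin remodelling complexes (chromosome 19, 49496819 to 49519227, plus strand), had the lowest FDR of them, 6.90e-12 in the authors' deposited table, for mutually exclusive exons. PRKDC, the catalytic subunit of the DNA-dependent protein kinase of end joining (chromosome 8, 48685672 to 48872738, minus strand), had 5 listed events and an FDR of 3.81e-06 in the authors' deposited table. A skipped exon of the replicative polymerase subunit POLD2 had an FDR of 1.25e-05, and an alternative 5′ splice site of RBBP8, which encodes the resection factor CtIP, had 5.96e-05 in the authors' deposited table. MDC1, the resection nuclease gene EXO1, BABAM1, a retained intron of ZSWIM7, TOPBP1, RNF8, RECQL4 and FANCM followed, between 6.11e-05 and 0.00484 in the authors' deposited table. By list, damage checkpoint and signalling had 12 of 57 symbols and homologous recombination and Fanconi 10 of 80. Base excision, mismatch and direct repair had 4 of 51, end joining 4 of 20 and nucleotide excision repair 1 of 29 (ERCC1). ILF2 itself was not listed.

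Ribosomal proteins and translation factors had 28 genes in the melphalan-treated knockdown comparison, led by EEF1D, RPL18 and RPL30, all printed at FDR 0, and RPS6 at 1.08e-09 in the authors' deposited table. Splicing regulators had 26 genes, led by PUF60 at a printed FDR of 0, HNRNPK at 2.36e-09 and SRSF6 at 2.48e-09 in the authors' deposited table. Cell cycle and mitosis genes also numbered 26, with the G1 regulators CDK6, CCNE1 and CDK4 and the condensin gene NCAPH2 at the top. Chromatin genes numbered 19, led by DAXX, EHMT2, WHSC1 and SMARCB1. The cleavage and polyadenylation gene CPSF1, at FDR 7.16e-13 in the authors' deposited table, led 8 RNA decay and 3′ end processing genes, ahead of CNOT7, CPSF4 and CNOT8. Apoptosis had 8 genes, led by DAP3, BID, DAXX and BCL2L12. Of 5 plasma cell and myeloma genes, NFKB2 had an FDR of 1.77e-10 in the authors' deposited table, followed by IKZF3, WHSC1 and CCND2. The 4 interferon response genes included IRF3, IRF7 and BST2, and POLK and GADD45A were the 2 p53 targets.

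The comparison of untreated with melphalan-treated cells asks which transcripts are spliced differently after the drug. It listed 1362 events in 988 genes, and 238 genes had more than 1 event. Skipped exons of C8orf59, the checkpoint kinase CHEK1, COX6C, the Polycomb gene EED, LSM1, MACC1, the replicative helicase subunit MCM6, NGLY1, the splicing factor PUF60 and RPL30 had a printed FDR of 0 in the authors' deposited table. A retained intron of UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex (chromosome 20, 44441215 to 44445596, plus strand), and mutually exclusive exons of the long non-coding RNA C17orf76-AS1 were also printed at 0 in the authors' deposited table. Skipped exons were the most frequent type with 975 events, followed by 294 mutually exclusive exons, 58 retained introns, 18 alternative 5′ splice sites and 17 alternative 3′ splice sites.

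DNA repair and damage signalling genes numbered 36 in the melphalan comparison. CHEK1 had 4 events. PRKDC had an FDR of 1.92e-10, RIF1, which limits end resection (chromosome 2, 152266397 to 152364527, plus strand), 1.41e-07, and RAD51AP1 (chromosome 12, 4647964 to 4669213, plus strand) 1.39e-05 in the authors' deposited table. UBE2A, POLD2, FANCD2, WDR48, LIG1, FANCI, UBE2T and RAD1 lay between 2.79e-05 and 0.00200 in the authors' deposited table. FANCD2 and FANCI form the complex that is ubiquitinated in interstrand crosslink repair, and UBE2T and WDR48 act in adding and removing that mark. By list, homologous recombination and Fanconi had 15 of 80 symbols and damage checkpoint and signalling 10 of 57. Base excision, mismatch and direct repair had 6 of 51, end joining 3 of 20 and nucleotide excision repair 2 of 29. ILF2 itself was not listed.

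Of the other lists, cell cycle and mitosis (166 symbols) had the most listed members in the melphalan comparison, 38 genes. These were led by MCM6, MCM5 at FDR 3.09e-12, CEP57 at 5.35e-12 and CEP192 at 1.73e-08 in the authors' deposited table. Splicing regulators numbered 32, led by PUF60, a retained intron of SRSF1 at FDR 3.92e-13, SRSF2 at 2.73e-07 and HNRPDL at 7.51e-07 in the authors' deposited table. Ribosomal proteins and translation factors had 22 genes, with RPL30, RPS6, EIF4G1 and RPL5 first. EED, SUV39H2, DNMT1 and KDM3B led 13 chromatin genes. The 11 apoptosis genes were led by ACIN1, BID, DFFA and DAP3. PAPOLA, at FDR 7.22e-10, and DIS3, at 1.60e-07 in the authors' deposited table, led 10 RNA decay and 3′ end processing genes, before CNOT10 and EXOSC1. DIS3, NFKB2, a retained intron of ATF4 and CD44 led 8 plasma cell and myeloma genes. Interferon response had 3 genes, among them IRF3 and IFI16, and p53 targets 1 (FAS).

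Skipped exons passed more often after melphalan than in either knockdown comparison, while mutually exclusive exons passed most often in the melphalan-treated knockdown comparison. The knockdown comparisons used 4 libraries each, but the number behind the melphalan comparison is not given. More libraries there would by themselves raise the percent that passed. Of the skipped exons tested, 3.43% passed in the melphalan comparison (95% exact binomial interval 3.22 to 3.64%), against 1.22% in the untreated (1.09 to 1.36%) and 1.28% in the melphalan-treated knockdown comparison (1.15 to 1.41%). The ratio of the melphalan to the untreated knockdown comparison was 2.81 (2.47 to 3.19, adjusted p = 1.48e-64), and that of the knockdown comparisons to each other was 1.05 (0.900 to 1.22, adjusted p = 0.660), by Fisher's exact test. For mutually exclusive exons, 13.1% passed in the melphalan-treated knockdown comparison, 7.24% in the untreated one and 5.49% in the melphalan comparison. The knockdown comparisons differed by a ratio of 1.81 (1.60 to 2.06, exact test, adjusted p = 1.12e-20). Alternative 5′ splice sites passed in 7.50% of tests in the melphalan-treated knockdown comparison and in 1.63% in the untreated one, a ratio of 4.61 (2.75 to 7.72, exact test, adjusted p = 6.88e-11).

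**Figure D1:**
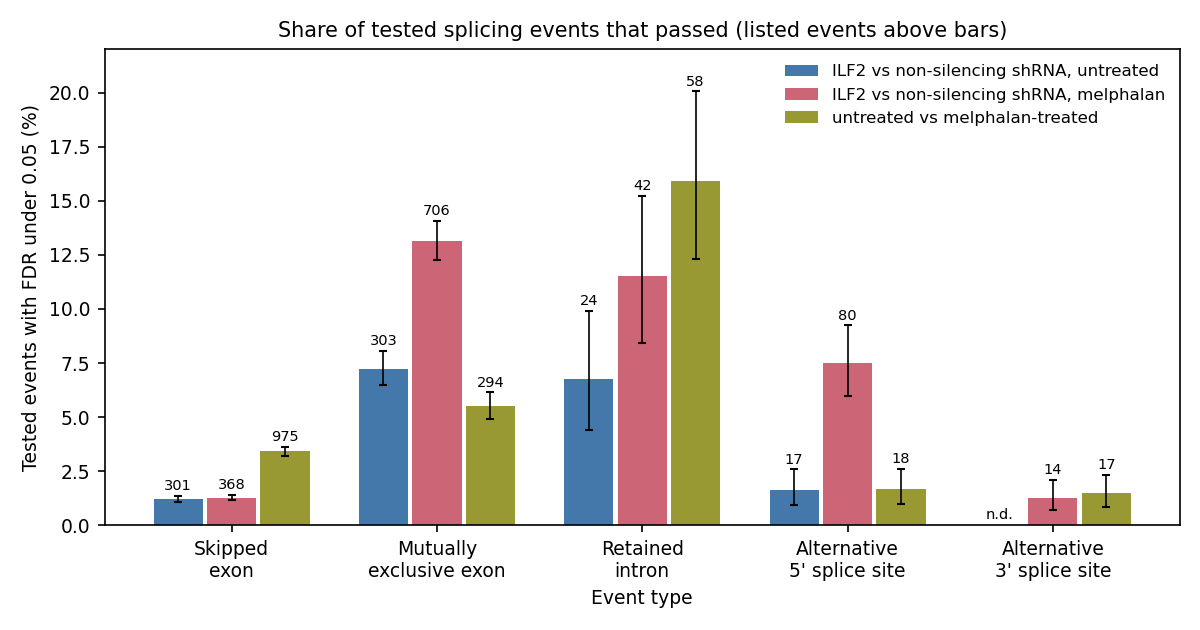
Percent of tested events with an FDR under 0.05 (vertical axis) for 5 event types (horizontal axis) in the 3 comparisons (colours). Bars give the percent, error bars the 95% exact binomial interval over events, and numbers above the bars the listed events; n.d. marks the alternative 3′ splice sites of the untreated knockdown comparison, whose number of tests could not be recovered. Mutually exclusive exons and alternative 5′ splice sites reached 13.1% and 7.50% in the melphalan-treated knockdown comparison.

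Retained introns, such as those of UBE2C, SRSF1 and ATF4, passed in 15.9% of tests in the melphalan comparison (12.3 to 20.1%), 11.5% in the melphalan-treated (8.42 to 15.2%) and 6.78% in the untreated knockdown comparison (4.39 to 9.92%). The ratio of the melphalan to the untreated knockdown comparison was 2.34 (exact test, adjusted p = 0.000274), but this call was lost at a fixed p of 0.0005 (adjusted p = 0.714). The knockdown comparisons differed in retained introns by a ratio of 1.70 (1.05 to 2.74) that did not pass after adjustment (exact test, adjusted p = 0.0550). Mutually exclusive exons passed less often in the melphalan than in the untreated knockdown comparison, with a ratio of 0.759 (exact test, adjusted p = 0.000896), a call that was also lost at the fixed p (adjusted p = 0.794). Of 13 such tests 8 passed after Benjamini-Hochberg adjustment. These tests run over events, which are not biological replicates, and do not measure the spread between libraries. They treat the comparisons as separate sets of events, since events tested in more than 1 comparison could not be matched. The melphalan comparison also reuses libraries of both knockdown comparisons, so its tests against them are not between independent sets.

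Counted as 1 event per gene and type, skipped exons made up 47.6% of the gene and type pairs in the untreated knockdown comparison, 32.3% in the melphalan-treated one and 68.8% in the melphalan comparison. Mutually exclusive exons made up 44.6%, 55.7% and 23.0% in the same order. Each pair of comparisons differed in both shares, with adjusted p values from 8.23e-63 to 6.89e-05 by Fisher's exact test. Shares add up to a whole, so the lower share of skipped exons in the melphalan-treated than in the untreated knockdown comparison did not come with a lower pass rate, which was 1.28% and 1.22%. The share of alternative 5′ splice sites was 6.67% in the melphalan-treated knockdown comparison, against 3.15% in the untreated one (adjusted p = 0.00603) and 1.67% in the melphalan comparison (adjusted p = 9.87e-09, exact tests). Between the knockdown comparisons the difference was 3.53 points, and at the fixed p it was 3.23 points and no longer passed (exact test, adjusted p = 0.0564). Retained introns took 4.44%, 4.12% and 5.10% and did not differ between any pair (exact tests, lowest adjusted p = 0.375). Of 15 tests 9 passed.

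DNM2, FDPS, PKM, CREBZF, CSDA and H2AFY had the strongest entries of the same type in both knockdown comparisons. DNM2 (chromosome 19, 10828731 to 10944164, plus strand), FDPS (chromosome 1, 155278539 to 155290457, plus strand) and PKM (chromosome 15, 72491370 to 72524160, minus strand) were printed at FDR 0 in both, and CSDA, a cold shock domain protein gene, at 1.60e-10 and 4.58e-13 in the authors' deposited tables. The macroH2A gene H2AFY had FDRs of 9.17e-10 and 0 in the authors' deposited tables. The knockdown comparisons shared 227 genes, 45.4% of the untreated and 24.5% of the melphalan-treated list. They share no library, but both set ILF2 against non-silencing shRNA in the same cell line. Sharing no library therefore does not make them independent. The untreated knockdown and melphalan comparisons shared 196 genes, the melphalan-treated knockdown and melphalan comparisons 347, and 116 genes were in all 3 lists, among 1761 listed in any. Every library of the series belongs to a knockdown comparison, so the melphalan comparison must reuse libraries of both. Part of the overlaps with it may come from these shared libraries. Independent lists of these sizes would share 227, 196 and 347 genes if drawn from 2042, 2520 and 2639 genes. The number of genes that could be tested is not given in the sources used here, so no enrichment over chance was computed.

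**Figure D2:**
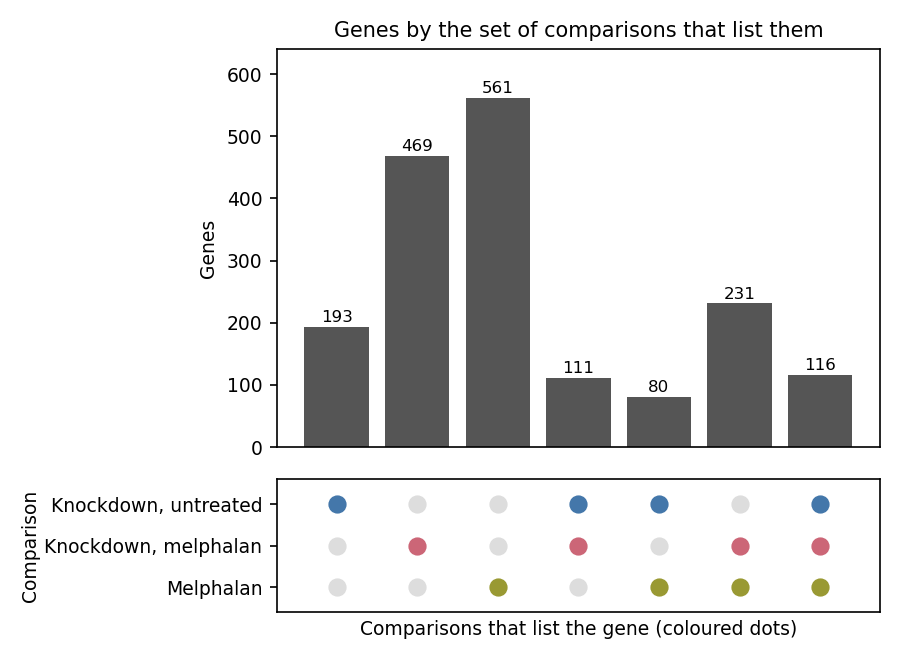
Number of genes (bars, vertical axis) listed in exactly the set of comparisons marked by the coloured dots under each bar. The melphalan comparison alone listed 561 genes, the melphalan-treated knockdown comparison alone 469, the untreated knockdown comparison alone 193, and all 3 comparisons 116.

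CHEK1, FANCD2 and TOPBP1 were the DNA repair and damage signalling genes listed in all 3 comparisons. CHEK1 was listed with a skipped exon each time, at FDR 0.000837 in untreated knockdown, 0.00756 in melphalan-treated knockdown and 0 after melphalan in the authors' deposited tables. FANCD2 (chromosome 3, 10068054 to 10143616, plus strand) was listed with mutually exclusive exons in untreated knockdown, at FDR 0.0184, and with skipped exons in the other lists, at 0.0357 and 0.000151 in the authors' deposited tables. TOPBP1, which activates the ATR checkpoint kinase (chromosome 3, 133317019 to 133381224, minus strand), had mutually exclusive exons in the knockdown comparisons and a skipped exon after melphalan. Without event coordinates it is unknown whether these are the same exons. The melphalan comparison reuses libraries of both knockdown comparisons, so listing in all 3 is not independent recurrence. ERCC1 was the only other gene of these lists found in both knockdown comparisons. Of 66 such genes listed anywhere, 8 were in the untreated knockdown comparison alone, 21 in the melphalan-treated one alone and 25 in the melphalan comparison alone.

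**Figure D3:**
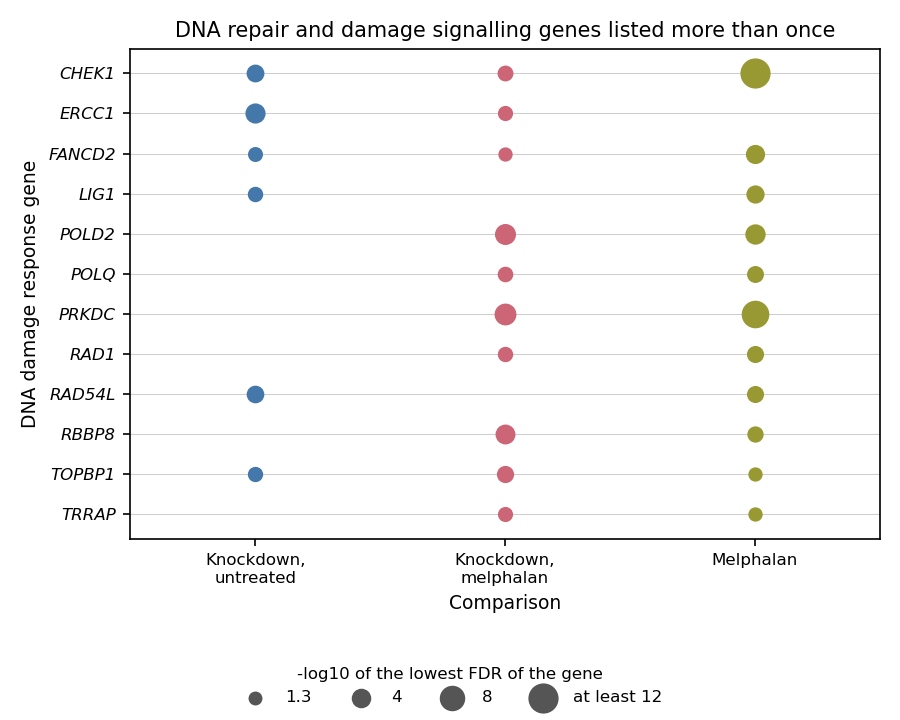
The 12 DNA repair and damage signalling genes listed in more than 1 comparison (vertical axis) by comparison (horizontal axis). A dot marks a listed gene and its area grows with -log10 of the gene's lowest FDR in the authors' deposited tables, held at 12 for lower values; CHEK1, FANCD2 and TOPBP1 have a dot in all 3 columns.

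The 5 DNA repair and damage signalling lists together held 2.80% of the genes of the untreated knockdown comparison, 3.34% of the melphalan-treated one and 3.64% of the melphalan comparison. None of these shares differed between comparisons after adjustment. Over 15 lists or pooled lists and 3 pairs of comparisons, 45 Fisher's exact tests gave 0 adjusted p values under 0.05 and 1 unadjusted one. That was the share of ribosomal proteins and translation factors, 4.60% in the untreated knockdown and 2.23% in the melphalan comparison (exact p = 0.0155, adjusted p = 0.699). Listed genes of a list could not be set against its unlisted members, whose p values are not in the tables used here.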

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

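The tests of depth, of 1 event per gene and of a fixed p were chosen only after the result was seen, as was the comparison of pass rates itself.

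The percent of tested events that passed differed between the knockdown comparisons with and without melphalan for 2 event types. Mutually exclusive exons, among them those of RUVBL2, NFKB2 and CPSF1, passed 5.90 percentage points more often in melphalan-treated cells. Alternative 5′ splice sites, among them those of CLDND1, RBBP8 and DAP3, passed 5.87 points more often. The test was of the difference itself, by Fisher's exact test over events. More events were tested in melphalan-treated cells, 28849 against 24698 skipped exons and 5373 against 4184 mutually exclusive exons, which goes with deeper libraries there, while tested alternative 5′ splice sites numbered 1067 against 1045.

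A depth difference that raised the pass rate of every type alike would have raised skipped exons too. Their ratio was 1.05 (0.900 to 1.22), below the lower bounds of 1.60 and 2.75 for mutually exclusive exons and alternative 5′ splice sites. Retained introns also passed more often, by a ratio of 1.70 (1.05 to 2.74) that did not pass after adjustment (exact test, adjusted p = 0.0550). Alternative 3′ splice sites could not be compared. The tested events, which are the denominators, also rose unequally by type, so these ratios cannot decide whether depth accounts for the difference. Several listed events of the same gene do not account for the difference. With 1 listed event per gene over all tested events, the ratios were 1.84 (1.59 to 2.12) and 3.92 (2.32 to 6.62). The tested events could not be reduced to 1 per gene. A more lenient p threshold in the longer list does not account for the difference either, since at a fixed p of 0.0005 the ratios were 1.74 (1.46 to 2.09) and 3.40 (1.92 to 5.99). With 0 columns of values per library, a single outlying library cannot be told apart from the treatment. Depth, library quality, a different strength of knockdown, and an effect of the ILF2 shRNA that differs under melphalan may each account for the difference. They were not told apart.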

How the results depend on the processing

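The fixed p of 0.0005, all pass rates and the matching by gene and type were chosen only after the result was seen; the other settings were planned. No paired analysis was possible because the tables hold no values per library. For that reason leaving out a library, regrouping libraries, minimum changes of inclusion, a junction read minimum, directions and overlap by coordinates were not run, and the depth behind each event stays unknown.

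At an FDR under 0.01 the untreated knockdown, melphalan-treated knockdown and melphalan comparisons held 347, 681 and 767 events, and under 0.001 they held 186, 397 and 383. The fixed p left 791 events in the melphalan-treated knockdown comparison. Genes shared fell at FDR under 0.01 to 113 between the knockdown comparisons, 97 and 155 between each of these and the melphalan comparison, and 48 in all 3. Matched by gene and type, 69 pairs of gene and type were in all 3. These losses follow from stricter thresholds or matching.

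The higher share of mutually exclusive exons in the melphalan-treated than in the untreated knockdown comparison kept direction and call at FDR under 0.01, at the fixed p and with all events. The share of alternative 5′ splice sites, melphalan-treated minus untreated knockdown, was 3.53 points and at the fixed p 3.23 points, which no longer passed (exact test, adjusted p = 0.0564). That of alternative 3′ splice sites passed with all events (1.00 points, exact test, adjusted p = 0.0391). In the melphalan minus the untreated knockdown comparison the share of alternative 3′ splice sites differed by 1.21 points (exact test, adjusted p = 0.0482). That call was lost at FDR under 0.01 (0.928 points) and at the fixed p (1.33 points, exact test, adjusted p = 0.0690). The share of retained introns, which differed in no test, turned to -2.08 and -1.64 points against the untreated and -0.0390 and -0.800 points against the melphalan-treated knockdown comparison, at FDR under 0.01 and at the fixed p.

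Pass rates of the melphalan minus the untreated knockdown comparison lost their call for mutually exclusive exons (-0.246 points at the fixed p, -0.0757 at FDR under 0.01) and for retained introns (1.48 and 2.85 points). Differences that passed no test changed sign for skipped exons between the knockdown comparisons (-0.0794 points, FDR under 0.01). Between the melphalan and the melphalan-treated knockdown comparison they did so for retained introns (-0.274, fixed p) and alternative 3′ splice sites (-0.0294, FDR under 0.01). For the calls lost and signs changed, the cause was not tested.

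DNA repair and damage signalling genes numbered 6, 17 and 21 at FDR under 0.01. Skipped exons alone gave 3, 12 and 30, and homologous recombination and Fanconi genes alone 3, 10 and 15. Over the 14 lists and 3 comparisons, 40 of 42 counts were lower at FDR under 0.01 and 34 with skipped exons alone, and 4 fell to 0 under each.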

Other observations

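Of the tests in this part, that of DNA repair and damage signalling genes was chosen only after the result was seen.

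Retained introns of UBE2C, C17orf76-AS1, MCM7, ATP5G3 and LUC7L3 were listed in all 3 comparisons, as were skipped exons of 45 genes and mutually exclusive exons of 19. MCM7, a subunit of the replicative helicase, had FDRs of 0.000262 in untreated knockdown, 0.000200 in melphalan-treated knockdown and 6.57e-06 after melphalan in the authors' deposited tables. UBE2C was near the cutoff in untreated knockdown, at 0.0498, with 1.18e-12 in melphalan-treated knockdown and 0 after melphalan in the authors' deposited tables. The skipped exon genes in all 3 included the splicing factors PUF60 and SRSF3, the translation factors EEF1D, EIF3A and EIF4G2, the replication factor CDC45, SYNCRIP, ZFR and the histone methyltransferase EHMT2. Mutually exclusive exons of BID, IRAK1, EIF4G1, RPL18 and RPS2 recurred likewise. No alternative splice site gene was listed with the same type in all 3. The melphalan comparison reuses libraries of both knockdown comparisons, so listing in all 3 is not independent recurrence.

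Some genes had many events. In untreated knockdown EIF4G1 had 12, FAM49B 11 and PPP6R3 10. In melphalan-treated knockdown FAM49B had 12, the interleukin receptor kinase IRAK1 8 and PIGT 7. After melphalan MORF4L2 had 9, the endocytic adaptor PICALM 8, and the kinetochore motor CENPE and FAM49B 7 each. All events of PICALM and CENPE there were skipped exons.

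Genes with more annotated exons have more events to test, a technical explanation for the 227 genes shared by the knockdown comparisons, such as DNM2, FDPS and PKM. Only 115 of them could be set against other genes, those among 981 genes of the melphalan list with an exon number. There the odds ratio of being in both knockdown lists was 3.48 in all and 3.47 within 5 bins of exon number, above all 10000 permutations within bins (highest 1.88, p = 0.0001, the smallest they can give). Exon number stays open for all 227, since the test leaves out the others and picks genes by a list that shares libraries with both. In 2 bins with fewer exons the odds ratio did not pass (Fisher's exact p = 0.0887 and 0.164). Whether genes recur whatever the event type was set against random re-pairing of types. A type in common was found for 181 shared genes (79.7%), against a median of 117 in 10000 random re-pairings. None of these reached as many (permutation p = 0.0001, the smallest they can give). Re-pairing lets a gene take types that may not have been tested in it, so the excess cannot decide this. High expression, which raises the power of every comparison, was not tested and may account for the overlap. So may any difference between ILF2 and non-silencing shRNA cells that both comparisons share, an effect of ILF2 depletion included.

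One hypothesis was that DNA repair and damage signalling genes recur less often between the knockdown comparisons than other genes. Of 14 such genes in untreated knockdown 4 (28.6%: CHEK1, ERCC1, FANCD2 and TOPBP1) were also listed in melphalan-treated knockdown, against 223 of 486 others (45.9%). The difference did not pass (Fisher's exact p = 0.278), and 14 genes are too few to tell.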
